A study of Homo sapiens with 9 samples.

How the data were processed

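RNA was measured in 9 libraries of sorted human thymocytes. The cells were immature single positive (ISP) CD28+ thymocytes, sorted as CD4+ CD28+ CD3− CD8−, a stage that has passed beta selection. They came from 3 independent donors. Per the labels' protocols, 100000 cells per well were cultured in 100 µL of medium with 20% FCS, 10 ng/mL SCF and IL-7, and were left unstimulated or stimulated for 24 h with 2.5 or 10 µL of ImmunoCult, a soluble antibody reagent that activates T cells through their surface receptors. Libraries were prepared with the QuantSeq 3′ mRNA FWD kit, per the labels' protocols, which reads the end of polyadenylated transcripts. The groups (0, 2.5 and 10 µL, 3 libraries each) and the donor numbers were taken from the labels. Replicate 1, 2 and 3 denote the same donor at each dose.

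The values used are raw read counts per Ensembl gene, deposited by the authors as whole numbers without normalization. Per the submitters' processing notes, STAR 2.4.2a, DESeq2 (version not given) and the builds GRCh38 and hg38 were used. The strand setting of the counting and the annotation release are not given in the sources used here, so a gene could not be separated from a gene overlapping it on the opposite strand. A second deposited table of normalized values was not used, because most of its values carry a point after every 3 digits and the place of the decimal is lost. The count table held 22840 genes and 4 summary rows. Of the reads in all rows, genes took 38.6% to 44.8%, reads without a gene feature 29.0% to 37.4%, multimapping reads 12.4% to 14.3%, unmapped reads 5.67% to 9.58% and ambiguous reads 3.30% to 4.27%. The summary rows stayed out of library sizes and tests. Y-linked genes, XIST and TSIX, 25 genes together, were removed before any fit, which left 22815 genes. The table held 0 genes of the mitochondrial chromosome. Of the gene IDs kept, 22348 were found in a gene name table, from which symbols were taken. Coordinates are those of the deposited file (GRCh38).

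Gene counts per library ranged from 2516143 to 4268761, and the genes with at least 1 count from 13025 to 17229. Replicates of a group differed by more than sampling noise in every pair (chi-square per degree of freedom 13.0 to 32.1). Counts carried no molecular identifiers in the sources used here, so intervals for counting error do not cover amplification.

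Genes were filtered with filterByExpr by group, which kept 12826, and libraries were scaled by TMM. Each dose was compared with 0 µL, and 10 µL with 2.5 µL, by edgeR's quasi-likelihood F test (edgeR 4.0.16 in R 4.3.3, robust fit, prior count 0.125), two-sided, with all 9 libraries in one fit of group means. A gene was called at a Benjamini-Hochberg adjusted p under 0.05, with no fold minimum. Standard errors and 95% intervals of log2 fold changes were derived from the F statistic. CPM values are TMM scaled, with mean ± SD over n = 3 donors. The fit without a donor term was fixed before the data were examined, and the donor block was tried beside it. The labels give the same 3 donors at each dose. Same-donor libraries deviated together from their group means, with correlations across genes of 0.0845 to 0.250 in 9 pairs, 6 of them above 0.1. The highest correlation with another donor ranged from −0.0574 to −0.0251, so each library correlated best with its own donor's. Deviations from a group mean cancel within the group, so a positive same-donor value lowers the others. The negative values are therefore not separate evidence of a donor effect. The blocked value is given beside a call that it changed and a count of genes, list members or lists that it moved by more than 1.5 times. Fits without a library or a donor were run without the block, except for the 2.5 µL library of replicate 2, which was also left out with it. The common dispersion was 0.257 without the block and 0.201 with it.

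Gene lists (25) and cell type marker lists (11) were written before the data were examined. The 32 lists with at least 3 tested genes were tested with limma's camera (limma 3.58.1, preset correlation 0.01), which compares a list with the other tested genes, with adjustment over the 32 lists. Camera with an estimated correlation, fry, and the blocked fit were alternatives. Named genes were fixed by rule. The first part takes up to 8 rising and 8 falling genes per comparison with the largest fold change among those called, with at least 10 CPM in the higher group and the same direction in 3 donors, leaving out unnamed clones, LINC, antisense and pseudogenes. The second takes up to 4 members of each list with the lowest p. The third is a fixed set: CD69, CD5, EGR1, NR4A1, RAG1, RAG2, PTCRA, TRAC, TRDC, CD3E, CD4, CD8A, CD28, IL2RA, MYC, MKI67, HOXA9, GATA3, RUNX1 and ETS1. Genes named outside the rule are marked as chosen after their values were seen.

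Other alternatives were DESeq2's size factors, library sizes without scaling, no expression filter, a filter of 5 CPM in 3 libraries, a prior count of 2, DESeq2 1.42.0 with and without the block, limma-voom, fits of only the 2 groups compared, and fits without each library or each donor. The overlap of calls between the doses was set against 40 simulations of unchanged groups, and, after the results were seen, against 40 more that kept the fitted differences between donors, each fitted without and with the block. The gene test was checked on simulated counts with 200 changed genes in 5 draws and 12017 to 12119 tested genes. For 10 against 0 µL it recovered 50.0% of genes changed by 2 on the log2 scale and 5.76% of those changed by 1, with 4.18% false calls. For 2.5 against 0 µL it recovered 51.1% and 7.68%, with 4.32% false calls. A list of 30 genes raised by 0.5 was called in 5 of 5 draws at each dose, and 0 of 100 unchanged lists were called. The simulated genes were drawn independently of each other and without donor differences. These list counts therefore do not cover real lists whose genes correlate, such as the S phase genes (estimated correlation 0.18 at 10 µL).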

Results

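RNA was sequenced from ISP CD28+ thymocytes of 3 donors, left unstimulated or stimulated for 24 h with 2.5 or 10 µL of ImmunoCult per 100000 cells. The 24 h was recorded for the stimulated libraries only, so an equal culture time of the unstimulated ones is not established here. ISP thymocytes stand between beta selection and the double positive stage, when the T cell receptor alpha locus rearranges. Each group held 3 libraries, 1 per donor. The total gene count was 3396308, 3413819 and 4268761 in the unstimulated libraries of replicates 1, 2 and 3, 3317091, 2516143 and 3605452 at 2.5 µL, and 2596985, 3581213 and 3494528 at 10 µL. At these totals 1 CPM corresponds to a few reads, so the levels of genes under about 10 CPM are imprecise. The 2.5 µL library of replicate 2 had the lowest total and the fewest genes with a count (13025, against 14840 to 17229 in the other libraries). It stood apart on the first principal component (131, against −33.3 to 9.89 in the others, with 27.8% of the variance) and had the lowest limma quality weight (0.515).

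The comparison of 10 µL with 0 µL asks which transcripts respond when the surface receptors of these cells are engaged. The chemokine genes XCL1 and XCL2 rose most among the called genes, by 6.58 ± 0.65 (SE) and 6.74 ± 0.72 on the log2 scale. XCL1 went from 0.585 ± 0.366 CPM (SD, n = 3) to 55.8 ± 16.3 CPM. TNFRSF9, which encodes the costimulatory receptor 4-1BB, rose by 4.61 ± 0.67, and EGR1, an immediate early transcription factor induced by receptor signalling, by 3.13 ± 0.47. RAG1, which encodes a subunit of the recombinase that rearranges antigen receptor genes, fell by 2.04 ± 0.28, from 316 ± 73.8 CPM to 76.9 ± 14.0 CPM. Each of these genes moved the same way in 3 of 3 donors.

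The test called 10 of 12826 genes, 8 higher and 2 lower (edgeR's quasi-likelihood test, Benjamini-Hochberg adjusted p under 0.05), and 479 genes had an unadjusted p under 0.05 (966 with the donor block). With no gene changed, a share of 0.05 of the tested genes would be expected to reach that. The count without the block lay below this share, so it is no sign of further changed genes, and the count with the block lay above it. The other called genes were the transcriptional repressor HIC1 (log2 fold change 3.80 ± 0.65), the TNF receptor gene TNFRSF1B (2.82 ± 0.51), the apoptosis inhibitor BIRC3 (1.87 ± 0.27), AHI1 (1.38 ± 0.24) and the sodium channel gene SCN3A (−1.32 ± 0.21). Adjusted p ranged from 4.05e-05 for XCL1 to 0.0304 for TNFRSF1B, and RAG1 had 0.00256. With the donor block 37 genes were called, 28 higher and 9 lower, the 10 genes among them, and 117 with the block but without the 2.5 µL library of replicate 2. The block added, among the named genes, the phosphatase genes DUSP4 (blocked log2 fold change 2.87 ± 0.56) and DUSP2 (1.30 ± 0.23), the adaptor SH2D2A, HLA-B (1.43 ± 0.22), the T cell receptor constant gene TRAC (1.27 ± 0.23), LTB, the glycolytic enzyme PKM, the chaperones HSPE1 and HSP90AA1, and GAR1 on the higher side. On the lower side it added ID1, an inhibitor of E proteins (−1.56 ± 0.28), and TP53INP1 (−1.04 ± 0.21).

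XCL1 and XCL2 lie on chromosome 1 at 168576473 to 168582077 and 168540765 to 168543997. They are near-identical copies, so the split of reads between them is uncertain. Their unstimulated libraries held 1 to 3 and 0 to 3 reads. The ratio of the pooled counts was 108 (95% interval 49.3 to 295) for XCL1 and 126 (48.7 to 463) for XCL2, for counting error alone. The fitted fold change depends on the prior count, and for XCL1 it was 5.62 with a prior count of 2. RAG1 (chromosome 11, 36510709 to 36593156) overlaps RAG2 (36575574 to 36598279) on the opposite strand, and HIC1 (chromosome 17, 2054154 to 2063241) overlaps SMG6, so these counts are uncertain to that extent. TNFRSF9 lies on chromosome 1 at 7915894 to 7943165, EGR1 on chromosome 5 at 138465490 to 138469315 and BIRC3 on chromosome 11 at 102317450 to 102339403. TRAC, as the file draws it, spans 22203093 to 22552155 on chromosome 14, an interval that holds TRDC and other genes of the alpha and delta receptor locus. HSPE1 overlaps HSPD1, and FEN1 overlaps TMEM258 and FADS2.

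**Figure D1:**
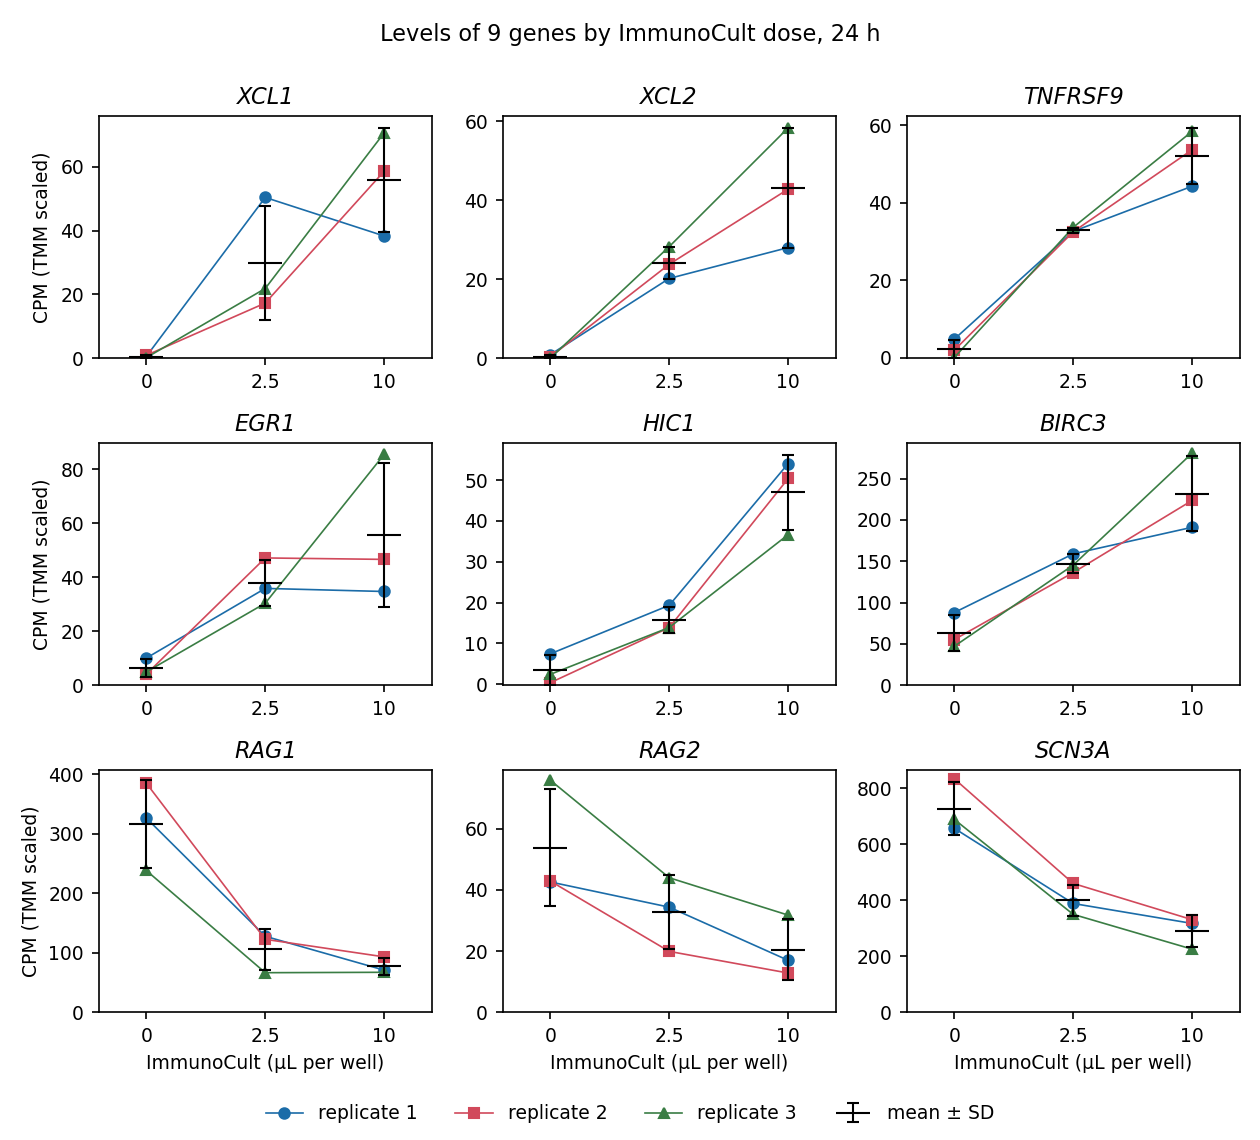
TMM-scaled CPM (linear vertical axes from 0) of 9 genes at 0, 2.5 and 10 µL of ImmunoCult, with 1 symbol and line per donor replicate and bars for the mean ± SD of 3 replicates. RAG1 had means of 316, 105 and 76.9 CPM in order of dose, and BIRC3 63.4, 147 and 232 CPM.

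Genes induced by receptor signalling were higher as a list, while most of them were not called singly. Of 34 immediate early and TCR-induced genes, 30 had a positive fold change (median 0.86), 2 rose and 0 fell over all genes (4 and 0 with the donor block), and 6 rose and 0 fell adjusted over the list alone (7 and 1 with the block; camera adjusted p = 1.95e-15). Cytokine and chemokine genes (13 of 15 positive, median 0.75) were also higher as a list (adjusted p = 1.27e-13). XCL1 and XCL2 rose over all genes. With IL32 (1.15 ± 0.31), TNFSF10 (1.07 ± 0.31) and LTB (0.75 ± 0.25), 5 rose adjusted over the list alone. NF-kB targets were 23 of 26 positive (median 0.67, adjusted p = 5.92e-09), with BIRC3 past the test over all genes and adjusted over the list alone (2 members each way with the block). Glycolysis and nutrient transport genes (22 of 26 positive, median 0.45, adjusted p = 4.70e-06) included LDHA at 0.69 ± 0.23 and ENO1 at 0.52 ± 0.20, and 0 members passed over all genes or adjusted over the list alone. Blocked by donor, 1 member, PKM, rose over all genes and 8 rose adjusted over the list alone. Interferon-stimulated genes were 26 of 40 positive (median 0.26, adjusted p = 0.000173), and IFI44L rose adjusted over the list alone (3.31 ± 0.90), a call lost with the block (adjusted p = 0.0509 over the list). These 5 lists passed with an estimated correlation as well, at adjusted p of 0.0119, 0.0120, 0.0143, 0.0143 and 0.0194. With the donor block as well, 4 of them held and the interferon-stimulated genes did not (adjusted p = 0.0944 with an estimated correlation and the block).

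Another 8 lists were higher with the preset correlation and missed the threshold with an estimated one in the fit without the block. With an estimated correlation and the donor block, 3 of them passed: S phase genes and costimulatory and inhibitory receptors (adjusted p = 0.0253 each) and MYC targets and ribosome biogenesis (0.0258). Genes of MYC targets and ribosome biogenesis (43 of 50 positive, median 0.43, adjusted p = 5.92e-09) had adjusted p = 0.0624 with an estimated correlation, and HSPE1 and SRM rose adjusted over the list alone (9 members with the donor block, and 2 over all genes, against 0). Costimulatory and inhibitory receptors (14 of 17 positive, median 0.51, adjusted p = 1.61e-07) had adjusted p = 0.0510 with an estimated correlation, and TNFRSF9 and TNFRSF1B rose over all genes and adjusted over the list alone. S phase genes (42 of 50 positive, median 0.33, adjusted p = 9.01e-07) had adjusted p = 0.200 with an estimated correlation, and 0 members passed by either adjustment. The block raised this to 12 members adjusted over the list alone and 0 over all genes. For TCR chain constant genes (6 of 6 positive, median 0.35) the adjusted p was 0.0200, and 0.112 with an estimated correlation, and TRAC rose adjusted over the list alone. Heat shock and dissociation stress genes (15 of 19 positive, median 0.15) had adjusted p = 0.0155, and 0.137 with an estimated correlation, and HSPE1 rose adjusted over the list alone (3 members with the block, and 2 over all genes). Amino acid response and serine synthesis genes (13 of 20 positive, median 0.18) had adjusted p = 0.0440, and 0.222 with an estimated correlation. Early T progenitor genes (8 of 13 positive, median 0.32) had adjusted p = 0.0440, 0.137 with an estimated correlation and 0.0791 with the donor block. KIT, the stem cell factor receptor, rose in that list adjusted over the list alone (2.56 ± 0.73). Regulatory T cell markers (2 of 3 positive, median 0.37) had adjusted p = 0.0166, and 0.112 with an estimated correlation. The member that rose adjusted over the list alone was IL2RA (2.39 ± 0.58), which is also induced on activated T cells.

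A further 2 lists were lower. Immature single positive to double positive stage genes had 17 of 21 negative fold changes (median −0.40, adjusted p = 2.25e-06, 0.0624 with an estimated correlation, and 0.0253 with an estimated correlation and the donor block). RAG1 fell over all genes, and RAG1 and RAG2 (−1.39 ± 0.42) fell adjusted over the list alone. With the donor block 10 members fell and 1 rose adjusted over the list alone, PTCRA and CD4 among those that fell. Without the block PTCRA, the pre-T cell receptor alpha chain, stood at −0.95 ± 0.33 and CD4 at −0.76 ± 0.37. The 3 tested genes of the HOXA cluster were negative (median −1.05, adjusted p = 0.0143, and 0.200 with an estimated correlation), with HOXA9 at −1.05 ± 0.61 and 0 calls by either adjustment.

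Several genes tied to activation or to the cell cycle were not called. CD69 had a log2 fold change of 0.11 (95% interval −0.96 to 1.19), CD5 0.16 (−0.48 to 0.80), MYC −0.01 (−1.26 to 1.23) and MKI67 −0.28 (−0.69 to 0.12). CD8A stood at 0.57 ± 0.69. The intervals were −0.80 to 0.20 for CD3E, −0.48 to 1.55 for CD28, −0.11 to 0.73 for TRDC, −0.08 to 0.91 for GATA3, −0.83 to 0.22 for RUNX1 and −0.49 to 0.37 for ETS1. NR4A1 was too low to be tested, with 6 reads in the 3 unstimulated libraries (0 to 5 per library). It had 32 reads at 2.5 µL, 31 of them in 1 library, and 18 at 10 µL (3 to 9 per library). NR4A3, of the same list and added here after its values were seen, was not called over all genes either. Its reads went from 2 unstimulated (0 to 2 per library) to 51 at 2.5 µL (14 to 21) and 119 at 10 µL (33 to 44). The ratio of its pooled counts at 10 µL was 69.0 (95% interval 18.7 to 577), for counting error alone. G2 and mitosis genes had 27 of 55 positive fold changes (median −0.03, camera adjusted p = 0.537).

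The remaining lists were not called without the block. With the donor block, 5 of them were: V(D)J recombination machinery (lower, median −0.02, adjusted p = 0.0743, and 0.0166 blocked), T lineage and TCR enhancer transcription factors (lower, median −0.11, 0.0826 and 0.0489), positive selection and mature thymocyte genes (higher, median 0.0004, 0.0904 and 0.0361), gamma-delta T cell markers (higher, 4 of 4 positive, 0.0780 and 0.0140) and myeloid and dendritic cell markers (higher, 5 of 6 positive, 0.118 and 0.0486). These 5 calls were lost with an estimated correlation and the block, at adjusted p of 0.128, 0.395, 0.198, 0.128 and 0.189. Camera adjusted p was 0.607 for CD3 and TCR signalling components, 0.868 for NOTCH targets, 0.506 for cholesterol synthesis, 0.984 for apoptosis regulators, 0.133 for p53 targets and 0.733 for cytosolic ribosomal proteins. Among markers of other cell types it was 0.0743 for cytotoxic CD8 T cells, 0.218 for NK and innate lymphoid cells and 0.733 for B cells, plasmacytoid dendritic cells and fibroblasts alike. The fibroblast list had a median of −0.64 and a mean of 0.20, and the plasmacytoid list a median of 0.11 and a mean below 0. NOTCH targets and apoptosis regulators had negative medians (−0.01 and −0.09) and tested upward.

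Without each of the 6 compared libraries in turn 7 to 8 genes were called, and the calls that ended were AHI1 and TNFRSF1B (5 of 6 omissions each) and HIC1 and SCN3A (3 of 6 each). Leaving out a whole donor left 2 to 4 genes and ended the calls of EGR1, BIRC3, AHI1, HIC1, SCN3A and TNFRSF1B in 3 of 3 omissions and of RAG1 and TNFRSF9 in 2 of 3, limma-voom ended those of XCL1, XCL2, TNFRSF9, EGR1, HIC1 and TNFRSF1B, and library sizes without scaling that of TNFRSF1B.

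**Figure D2:**
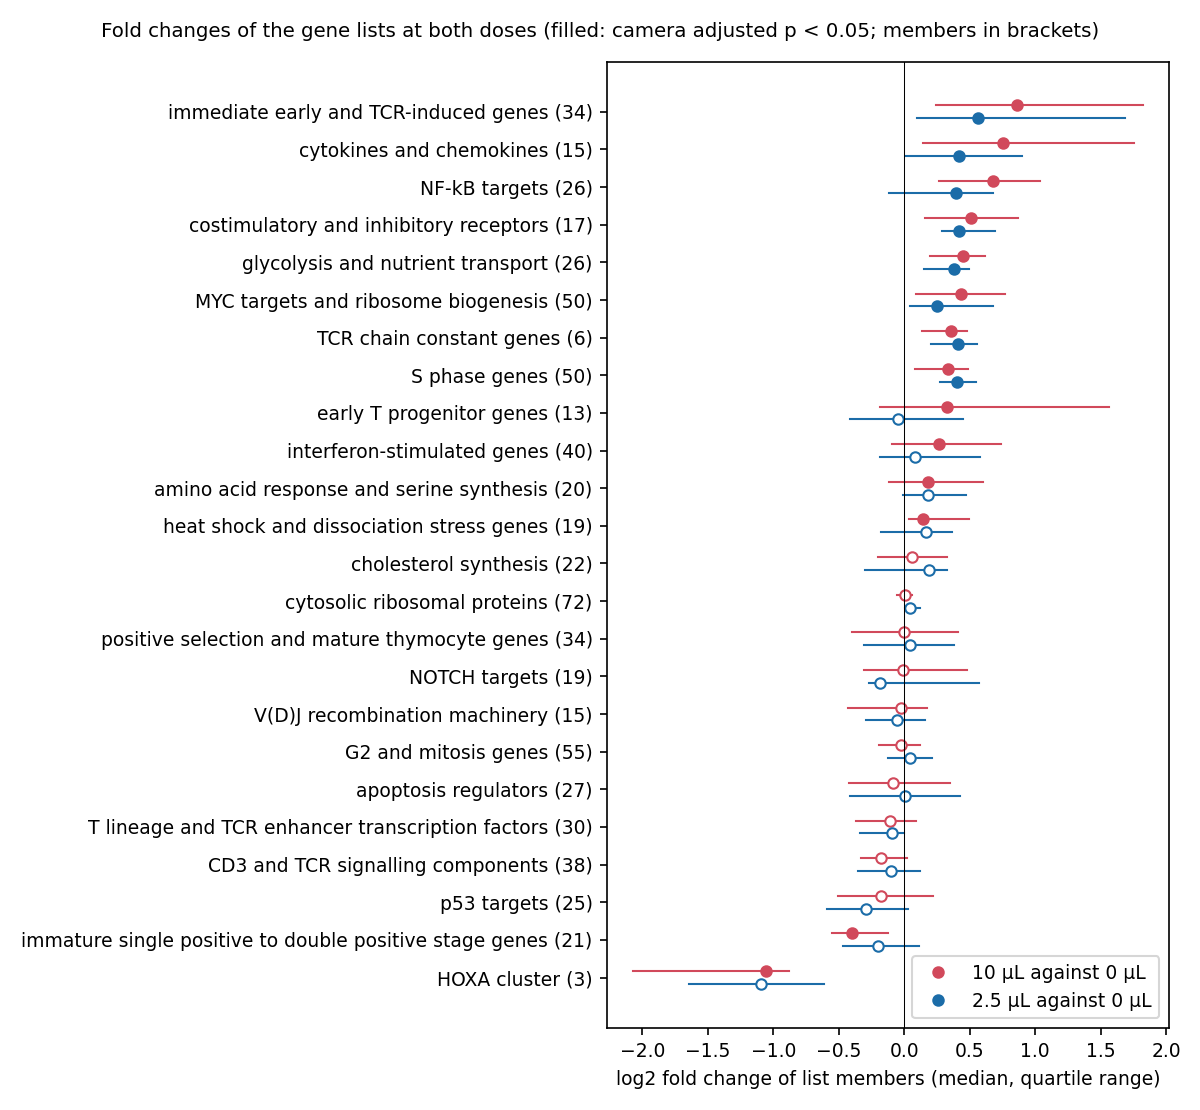
Median log2 fold change (points) and quartile range (lines) of the members of each gene list against 0 µL, at 10 µL (red) and 2.5 µL (blue), with the number of tested members in brackets. Filled points mark lists with a camera adjusted p under 0.05 (preset correlation); immediate early and TCR-induced genes had medians of 0.86 and 0.56.

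The comparison of 2.5 µL with 0 µL asks which transcripts change at the lower dose. XCL1 rose by 5.68 ± 0.64 on the log2 scale, XCL2 by 5.90 ± 0.71 and TNFRSF9 by 3.94 ± 0.66, and RAG1 fell by 1.59 ± 0.28. XCL1 reached 29.8 ± 17.9 CPM (SD, n = 3) and TNFRSF9 32.9 ± 0.6 CPM, from 2.21 ± 2.38 CPM. The ratio of pooled counts was 57.5 (95% interval 26.1 to 158) for XCL1 and 68.0 (26.2 to 252) for XCL2, for counting error alone. These 4 genes, 3 higher and 1 lower, were the calls among 12826 tested genes (edgeR's quasi-likelihood test, adjusted p of 0.000374, 0.000521, 0.0394 and 0.0464), and 539 genes had an unadjusted p under 0.05 (1079 with the donor block). The first count lay below the share of 0.05 expected with no change, and the blocked count above it. With the donor block 13 genes were called, 11 higher and 2 lower, the 4 among them, and 22 with the block but without the 2.5 µL library of replicate 2. Of the named genes the block added EGR1 (blocked log2 fold change 2.58 ± 0.45, adjusted p = 0.0128, against 0.0523 without the block), BIRC3 (1.23 ± 0.21), TRAC (1.38 ± 0.23), HSPE1, the flap endonuclease FEN1 (0.78 ± 0.16) and the D-type cyclin CCND3 (0.73 ± 0.14), which rose. SCN3A fell with the block by 0.87 ± 0.13.

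As a list, S phase genes had 46 of 50 positive fold changes (median 0.40, camera adjusted p = 1.97e-10), with MCM7 at 0.59 ± 0.20 and MCM4 at 0.62 ± 0.21. Its adjusted p was 0.152 with an estimated correlation and 0.0218 with an estimated correlation and the donor block. Of its members 0 passed by either adjustment, and with the block 14 rose adjusted over the list alone and FEN1 over all genes. G2 and mitosis genes had 31 of 55 positive (median 0.04, adjusted p = 0.259). Immediate early and TCR-induced genes (27 of 34 positive, median 0.56, adjusted p = 4.92e-09), cytokines and chemokines (11 of 15, median 0.42, 1.90e-07) and glycolysis and nutrient transport (21 of 26, median 0.38, 0.000167) were higher and held with an estimated correlation, at adjusted p of 0.0438, 0.0443 and 0.0443. With an estimated correlation and the donor block these calls were lost (adjusted p of 0.0723, 0.0642 and 0.0723). Over all genes 1, 2 and 0 of their members rose, and 4, 3 and 0 adjusted over the list alone. With the donor block 2, 2 and 0 rose over all genes, and 8, 4 and 7 adjusted over the list alone, where 1 glycolysis and nutrient transport gene fell. Costimulatory and inhibitory receptors (15 of 17, median 0.42, 3.40e-06), MYC targets and ribosome biogenesis (40 of 50, median 0.25, 6.97e-06), TCR chain constant genes (6 of 6, median 0.41, 0.00127) and NF-kB targets (17 of 26, median 0.39, 0.00474) were higher. Their adjusted p was 0.101, 0.152, 0.0800 and 0.152 with an estimated correlation. Adjusted over the list alone, 2, 2, 2 and 1 of their members rose, against 1, 0, 0 and 0 over all genes (1 in each with the block).

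The other 24 lists were not called. Immature single positive to double positive stage genes had 14 of 21 negative fold changes (median −0.20, adjusted p = 0.0908, and 0.0211 with the donor block). The block also called gamma-delta T cell markers (0.00929, against 0.0951) and cytosolic ribosomal proteins (57 of 72 positive, 0.00929, against 0.0908) as higher and T lineage and TCR enhancer transcription factors (0.0427, against 0.0908) as lower. These 4 calls were lost with an estimated correlation and the block, at adjusted p of 0.185, 0.142, 0.551 and 0.357. IL2RA had a log2 fold change of 2.03 ± 0.58, PTCRA −0.48 ± 0.33, RAG2 −0.71 ± 0.42 and CD69 −0.53 ± 0.52, none called. Without any of the 2.5 µL libraries (replicates 1, 2 or 3), the 10 µL libraries of replicates 1 or 2 or the unstimulated library of replicate 2, the calls of TNFRSF9 and RAG1 ended and 2 genes were left; without the unstimulated library of replicate 1 the RAG1 call ended. A fit of only these 2 groups called 0 genes (3 with the donor block, without TNFRSF9 and XCL2), leaving out a donor ended the calls of TNFRSF9 and RAG1 in 3 of 3 omissions and of XCL1 and XCL2 in 1 of 3 each, limma-voom those of XCL1, XCL2 and TNFRSF9, the filter of 5 CPM those of TNFRSF9 and RAG1, and library sizes without scaling that of TNFRSF9.

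Direct comparison of 10 µL with 2.5 µL tests whether the doses differ. The test called 0 genes with edgeR without the block and 0 with it, with a smallest adjusted p of 0.928 (0.566 with the block). An unadjusted p under 0.05 was reached by 228 genes (487 with the block), and DESeq2 called 1 (2 with the block) and limma-voom 0. The counts of 228 and 487 both lay below the share of 0.05 expected with no change. Among the genes called at 10 µL, a choice that favours a larger difference at that dose, HIC1 was higher than at 2.5 µL by 1.58 (95% interval 0.37 to 2.80), BIRC3 by 0.66 (0.12 to 1.20) and AHI1 by 0.52 (0.02 to 1.01), in 3 of 3 donors each, before adjustment. For XCL1 the interval was −0.05 to 1.85, for TNFRSF9 −0.48 to 1.81, for EGR1 −0.31 to 1.44 and for RAG1 −1.03 to 0.12. As lists, NF-kB targets (20 of 26 positive, median 0.28) and early T progenitor genes (10 of 13, median 0.42) were higher at 10 µL, and immature single positive to double positive stage genes (17 of 21 negative, median −0.25) lower, each at a camera adjusted p of 0.0302. With an estimated correlation the adjusted p was 0.339, 0.339 and 0.479, and 0 members passed over all genes or adjusted over the list alone. The donor block called 6 lists, adding cytokines and chemokines as higher (0.0428, against 0.0601) and G2 and mitosis genes (0.0348, against 0.0751) and cytosolic ribosomal proteins (0.0348, against 0.140) as lower. With an estimated correlation and the block the adjusted p was 0.303, 0.558 and 0.901 for these 3 lists and 0.303 for each of the other 3. The block without the 2.5 µL library of replicate 2 called 0 lists.

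The calls at both doses overlapped. XCL1, XCL2, TNFRSF9 and RAG1, that is 4 genes, were called at each dose in the same direction, and 11 with the donor block. Both comparisons share the 3 unstimulated libraries. In 40 simulations with no change in any gene and no donor differences the overlap averaged 0.025 and was at most 1, and in 40 with donor differences and the block it averaged 0.05 and was at most 1. Lists drawn independently would share 0.00187 higher and 0.000156 lower genes (0.0240 and 0.00140 with the block). Across genes, which are not independent replicates, the fold changes at the doses correlated with r = 0.530, against a simulated mean of 0.490 (0.461 to 0.519). Their covariance was 0.340, against a simulated mean of 0.354 (0.326 to 0.373), and 70.5% of genes had the same sign, against 66.5% (65.7 to 67.5%). In the fit with the donor block the correlation was 0.549 and the covariance 0.459, against 0.494 (0.467 to 0.530) and 0.340 (0.310 to 0.375) in the simulations with donor differences. The covariance thus lay within the simulated range without the block and above it with the block. The simulations share the controls too, but change no gene, so few calls and a small overlap are built into their setting. They do not give the overlap that shared controls add where genes do change. With 3 unstimulated libraries the controls could not be split into parts of at least 2. Part of the overlap may therefore come from the shared controls.

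**Figure D3:**
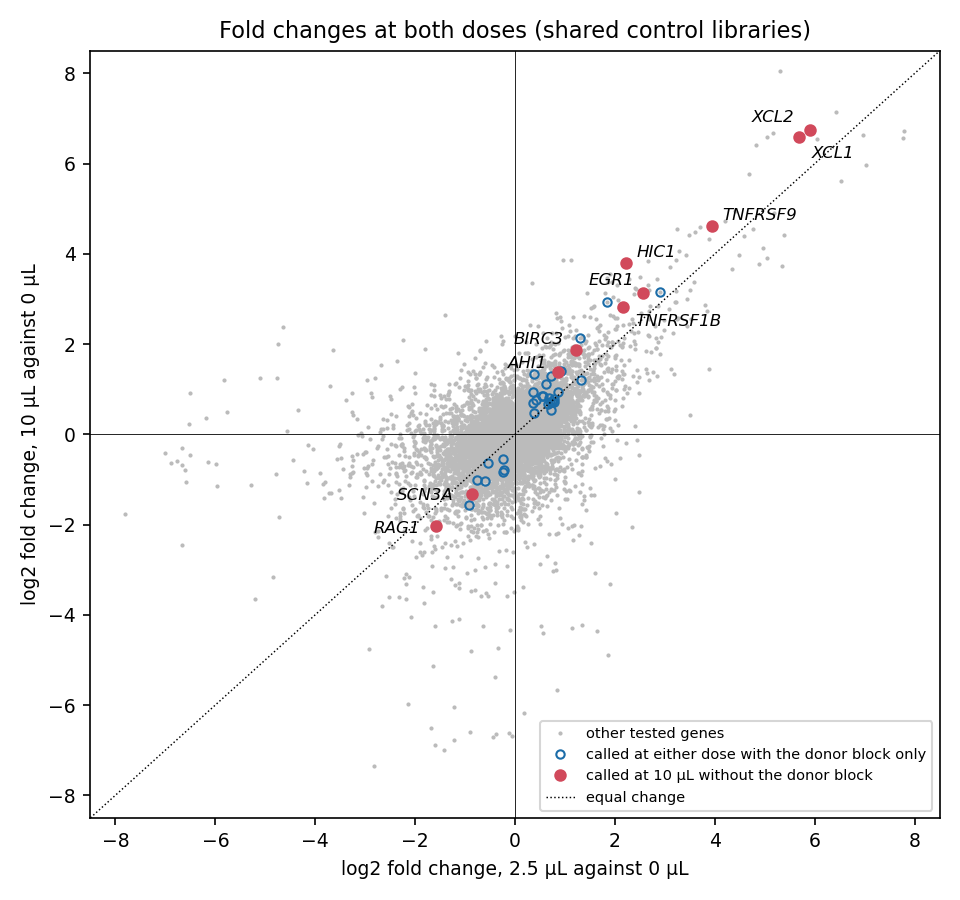
Log2 fold change of every tested gene at 2.5 µL (horizontal) and 10 µL (vertical), each against the same 3 unstimulated libraries. Red points are the 10 genes called at 10 µL without the donor block, open blue circles those called at either dose with the block alone, and the dotted line marks equal change.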

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

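The tests of XCL1, XCL2 and TNFRSF9, of RAG1, of cycling cells and of other splits of the libraries were chosen after the results were seen; the tests of the S phase genes against expression level and against single donors were written before.

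At 10 µL XCL1, XCL2 and TNFRSF9 rose in 3 of 3 donors. More NK or cytotoxic T cells in the stimulated wells would raise their transcripts with XCL1. The summed CPM of NKG7, GNLY, PRF1, GZMA, GZMB and KLRD1 went from 33.7 ± 9.0 to 39.0 ± 11.0, a difference of 5.36 (SE 8.21), against 55.2 (SE 9.43) for XCL1. GNLY alone went from 6 reads to 26 (0 to 20 per library). Adjusted over the list alone, 1 of 5 NK and innate lymphoid markers rose and 0 fell. That member was KIT, the stem cell factor receptor, which is also in the early T progenitor list and so does not single out NK cells. Of 7 cytotoxic CD8 T cell markers 0 rose so adjusted, and with the donor block 2 rose and 1 fell. Given the SE of 8.21 of the summed transcripts, a small rise of such cells is not excluded. Reads moved between the near-identical genes XCL1 and XCL2 would leave their sum in place, and the sum rose by 6.14 (SE 0.54) on the log2 scale with 0.5 CPM added. A response of a few mature T cells present at every dose remains open, since CCR7, IL7R and CD3E stood at 52.5, 150 and 187 CPM in unstimulated wells and thymocytes express these genes too; the sort removes CD3+ cells. A response of the ISP cells themselves to stimulation is the biological explanation the design gives, and it may stand beside that of mature cells.

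RAG1 fell at 10 µL in 3 of 3 donors. Reads moved to RAG2, which overlaps it on the opposite strand, would raise RAG2, whose log2 fold change had an upper 95% limit of −0.50. A lower share of immature thymocytes would lower the genes of that stage alike only if all were equally restricted to it. The other 20 tested genes of the immature single positive to double positive list had a median of −0.40 (SD 0.54). RAG1 lay below each of the 20, the lowest of which stood at −1.39. But RAG1 was examined because it fell most among the called genes, so its place follows in part from that choice. The comparison therefore cannot decide whether the share of immature cells fell. A regulated loss of RAG1 transcript after receptor stimulation may account for the fall and is a hypothesis from the same data.

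S phase genes were higher as a list at both doses, with medians of 0.33 and 0.40. The medians lay at percentile 100 of 10000 random lists matched for expression, whose highest medians were 0.21 and 0.23, which argues against a trend with expression level. Without any donor the lowest median was 0.30, which argues against a single donor. A larger share of cycling cells would raise S phase and G2 and mitosis genes alike, whereas within donors the S phase mean moved above the G2 and mitosis mean by 0.32 (SD 0.02) at 10 µL and 0.33 (SD 0.18) at 2.5 µL, in 3 of 3 donors each. A shift of cycling cells toward S phase may fit these values, and with an estimated correlation the list passed the threshold with the donor block (adjusted p = 0.0253 at 10 µL and 0.0218 at 2.5 µL) and missed it without (0.200 and 0.152), so the call depends on taking the pairing of donors into account.

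The 6 libraries of each comparison make 10 splits, too few for a share under 0.05. The real split of 10 against 0 µL called 10 genes and 15 lists, and the highest other 0 genes and 5 lists, so 1 split, the real one, gave as many of each. For 2.5 against 0 µL the real split called 4 genes and 8 lists, the highest other 0 and 5, and again 1 split gave as many. For 10 against 2.5 µL the real split called 0 genes by edgeR (228 at an unadjusted p under 0.05, 487 with the block, 1 gene by DESeq2, 0 by limma-voom), as did all 10 splits, and 3 lists, against 4 in the highest other, with 2 splits as large. Among the 4 splits that keep donors paired, with the donor block, the real counts of genes were 37, 13 and 0 and the highest others 0 in each comparison. Their counts of lists were 19, 12 and 6, and the highest others 4, 2 and 4.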

How the results depend on the processing

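Quality weights and the block without the 2.5 µL library of replicate 2 were alternatives chosen after the data were seen. Genes called at 10 against 0 µL (10) became 37 with the donor block, 35 with the block in a fit of only the 2 groups, 19 with no filter, 26 with DESeq2, 116 with DESeq2 and the block, 4 with limma-voom, 168 with limma-voom, quality weights and the block, and 117 with the block without that 2.5 µL library. Leaving out a library or a donor gave 2 to 12. At 2.5 against 0 µL (4) the counts in the same order were 13 (block), 8 (no filter), 12, 102, 1, 113 and 22, with 2 under the filter of 5 CPM, 0 in a fit of only the 2 groups (539 at an unadjusted p under 0.05 in the fit of all 9 libraries, 1079 with the block), and 1 to 4 without a library or a donor. At 10 against 2.5 µL edgeR called 0 genes (228 unadjusted, 487 with the block), DESeq2 1, DESeq2 with the block 2, limma-voom 0, and limma-voom with quality weights and the block 3. DESeq2 with the block gave no adjusted p to 9200 genes at 10 µL and 10692 at 2.5 µL.

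Lists called at 10 µL (15) became 5 with an estimated correlation, 8 with that and the block, and 5 with fry. At 2.5 µL (8) they became 3, 1 and 1, and 13 with the block without the 2.5 µL library. Between the doses (3) they became 6 with the block, 0 with an estimated correlation, with or without the block, 0 with fry, 0 with the block without that library, and 0 to 5 without a donor. The overlap of calls (4) became 11 with the block. The cause of these differences was not tested, except that a fit without a donor or a library holds fewer samples. DESeq2's size factors left the gene and list counts within 1.5 times, and plain library sizes the gene counts. Plain library sizes and the filters were not run on lists, and the overlap was recomputed with the block alone. Over the named genes 1878 single values kept their side of the threshold, 117 passed it and 78 no longer did. Among the 1878, 69 values of 20 results changed sign, none of them called with or without the alternative; 0 called values changed sign. Besides the calls given with their blocked value, the block changed no other call over all genes or of a list among the results printed. With 3 libraries per group at this depth and spread between replicates, genes that change by 1 on the log2 scale are mostly missed (5.76% recovered in simulation). The simulation did not separate the part of depth from that of the spread.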

Other observations

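The gene groups below were chosen after the called genes were seen, and called members were left out of them; the tests themselves were written before their results were seen. At 10 µL the nuclear-encoded genes of the respiratory chain, which carries electrons in mitochondria, had 67 of 81 positive fold changes (median 0.23, camera adjusted p = 3.63e-07, and 0.146 with an estimated correlation). The spliceosomal Sm and LSm genes, core proteins of splicing particles, had 17 of 17 positive (median 0.37, adjusted p = 4.35e-06, and 0.107 with an estimated correlation). MHC class I genes, which serve antigen presentation, had 10 of 11 positive (median 0.38, 0.00603, and 0.146 with an estimated correlation), and proteasome subunit genes 30 of 38 (median 0.22, 0.00264, and 0.146 with an estimated correlation). With an estimated correlation and the donor block the adjusted p was 0.0493 for the respiratory chain, Sm and LSm and MHC class I groups and 0.0635 for the proteasome. With the preset correlation and the block it was 1.44e-10, 4.64e-08, 0.000188 and 0.000272 in the order respiratory chain, Sm and LSm, MHC class I and proteasome. A rise of these groups with stimulation may hold. For the first 3 the call with an estimated correlation (0.146, 0.107 and 0.146 without the block) depends on taking the pairing of donors into account, and for the proteasome it turns on the correlation assumed.

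At 2.5 µL the respiratory chain group had 68 of 81 positive (median 0.26, adjusted p = 5.92e-09, and 0.102 with an estimated correlation) and the Sm and LSm group 17 of 17 (median 0.33, 2.53e-07, and 0.0694). The proteasome and MHC class I groups had adjusted p of 0.333 and 0.259. TRAV and TRAJ segments, the parts joined when the alpha chain rearranges, had 2 of 4 tested members positive at 10 µL (median −0.01, adjusted p = 0.618, and 0.631 with an estimated correlation), with 420 summed counts unstimulated and 361 at 10 µL. At 2.5 µL 3 of 4 were positive (median 1.02, adjusted p = 0.259, and 0.407 with an estimated correlation). With 4 members tested, whether segments followed TRAC stays open.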
